A study of Mus musculus with 4 samples.

How the data were processed

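The samples were 4 sections of pancreas from 4 mice, 1 section per mouse, measured with the Visium assay for fixed tissue, which counts probe pairs captured on barcoded spots. Per the labels, all mice carried a pancreas-specific Cre, a Kras allele and a Gnas transgene under control of doxycycline. Mice on doxycycline feed received 60 ppm from week 8 for 14 weeks, up to collection at week 22. The other group had normal feed and was collected at the same age. Each group held 2 sections. Per the labels, 3 mice were male, and the mouse of doxycycline feed 2 was female. No paired analysis was made, because the groups held different mice and the replicate numbers 1 and 2 are not said to tie mice across groups.

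The deposited values were raw UMI counts per gene and spot, produced with Space Ranger 2.1.0 on mm10 per the submitters' processing notes. The deposited matrices were the filtered ones by their names, and no header or label records any other filter or scaling. No positions of spots on the tissue were used, so nothing below describes distances. The matrices listed 19465 genes, of which 19106 had a symbol in the reference gene table, and 22 symbols were carried by more than 1 gene ID. Gene positions come from that table, which is on GRCm38, the assembly behind mm10.

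Total UMIs per section were 9840974 and 13855439 with normal feed and 20814271 and 65131651 with doxycycline feed. Spots numbered 3645, 4047, 3677 and 3236 in the same order, of which 2951, 3326, 3221 and 2468 had at least 500 UMIs. A background floor was computed as the median CPM of 1178 olfactory and vomeronasal receptor genes, which pancreas is not known to use. CPM here are UMIs of a gene per 1000000 UMIs of the section. For keratin-rich spots and regions, defined below, they are per 1000000 UMIs of those spots. Shares within a single section have exact Clopper-Pearson intervals at 95%, which cover counting error only, and a share of 0 is given with the limit set by 3 counts.

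Whole sections were compared by summing UMIs over all spots of each section. Genes were tested in edgeR 4.0.16 with TMM factors, its default filter on low counts and the quasi-likelihood test. P-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. The section was the replicate, so these p-values measure spread between mice. The same test was run on keratin-rich spots, the 10% of spots of each section with the highest share of UMIs from Krt7, Krt8 and Krt19. Krt18 had also been planned and was not among the genes of the files. The keratins chose these spots and are no independent result there.

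Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists with at least 3 tested members. With 4 sections the test at an estimated correlation rests on few residual degrees of freedom, so it can hardly call a list. The simulations below did not include it. A list not called with it is thus not shown to be unchanged. Of 35 lists, the mitochondrial list had no member in the files, which left 34 for whole sections and 33 for keratin-rich spots. A number of planned members were also missing from the files, among them Cpb1, Ldha, Isg15 and Hba-a1. Irag2 and Gif were present as Lrmp and Cblif.

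Regions were clusters of all spots with at least 500 UMIs, made in scanpy 1.11.5 without integration of sections. Counts per spot were scaled to 10000 and logged, 2000 variable genes were picked within sections, and 30 principal components with 15 neighbours entered Leiden clustering at resolution 0.5. Regions are called by their leading genes, ranked by fold against all other spots with 10 CPM added. A test within regions was planned for regions with 30 spots in all 4 sections. None met this (0 of 14 regions), so it could not be run as planned. In its place, doxycycline feed 1 was compared with both normal sections in the 7 regions with 30 spots in these 3 sections, a choice made after the data were examined. That comparison has 1 section on doxycycline feed, which is assumed to vary like the normal ones.

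Co-occurrence is Spearman's rho across the spots of a section between the UMI shares of a pair of lists, after every spot with at least 1000 UMIs was thinned to 1000. It was computed for 45 pairs. Spots are not replicates, so no p-value is given for it. The share of spots with a UMI of a gene used the same thinned counts. With 2 against 2 sections, the smallest two-sided exact permutation p is 0.333, so single values per section are given without a test.

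The fits were tested on simulated counts drawn for the real genes from the sections' means, totals and spread, with 200 genes changed by 4 or 16 fold. With the spread among all 4 sections, the whole-section fit on 19102 genes recovered 3% of the 4-fold and 64% of the 16-fold changes, and 8 of 75 calls were unchanged genes. With the spread without doxycycline feed 2, on 19123 genes, 89% and 100% were recovered, and 5 of 203 calls were unchanged genes. The keratin-rich fit on 13825 genes recovered 10% and 90%, with 2 unchanged genes among 102 calls. Without doxycycline feed 2, on 14541 genes, it recovered 94% and 100%, with 9 unchanged genes among 212 calls.

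The gene lists, the rule for naming genes, the tests and most alternatives were fixed before the data were examined. The rule named Gnas and Kras, and the genes with the largest changes past the threshold. Where none passed, it named the 5 genes with the smallest p in each direction, said not to pass. It also named, of each list described, the 3 members with the highest mean CPM and the one with the smallest p, and the 5 leading genes of each region. Alternatives were DESeq2 1.42.0 with its Wald test, other scalings, no filter on low counts, the acinar list left out, sex as a covariate, limma on the mean CPM per spot, other choices of spots and each section left out in turn. The sex term left 1 residual degree of freedom. Only doxycycline feed 2 was female, so this term fits that section by itself. The diet difference then rests on doxycycline feed 1 against both normal sections, as when doxycycline feed 2 is left out. Sex cannot be separated from that section. Alternatives chosen after the data were examined kept only genes at 5 times the floor in 2 sections or more, left out the lymphoid region, or took keratin-rich spots from those with 2000 UMIs. Computation used R 4.3.3 and Python 3.11.15.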

Results

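Gene expression was measured by Visium in pancreas sections of mice with altered Kras and a doxycycline-controlled Gnas transgene, a model of mucinous pancreatic tumours named in the series title. The groups were 2 sections from mice on doxycycline feed and 2 from mice on normal feed. Totals per section ran from 9840974 to 65131651 UMIs. Median UMIs per spot with at least 500 UMIs were 2830 and 3539.5 with normal feed, 4876 in doxycycline feed 1 and 25448 in doxycycline feed 2. Median genes per spot were 841, 1517, 1996 and 6077. Doxycycline feed 2, from the only female mouse, stood apart from the other sections in depth and in profile. Across the 19143 genes tested, its Pearson r of log2 CPM with the others was 0.669 to 0.816, against 0.942 to 0.979 among the other 3 (genes are not independent replicates). Its background floor was 0.399 CPM, against 4.57, 4.47 and 4.16 in normal feed 1, normal feed 2 and doxycycline feed 1.

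Gnas encodes the stimulatory G protein alpha subunit, and Kras a small GTPase of growth factor signalling. Gnas (chromosome 2, 174284320 to 174346744 on GRCm38) was at 252 and 409 CPM with normal feed and at 369 and 790 CPM with doxycycline feed. The group means were 330 ± 111 and 579 ± 298 CPM (SD, n = 2). Kras (chromosome 6, 145216699 to 145250420) was at 11.8 and 29.5 CPM with normal feed and at 28.7 and 78.0 CPM with doxycycline feed. The groups overlapped for both genes, and neither passed the test of edgeR in whole sections (adjusted p 0.747 and 0.627). In keratin-rich spots Gnas was at 407 and 505 CPM with normal feed and 475 and 739 CPM with doxycycline feed, and did not pass in edgeR (adjusted p 0.472). Kras did not overlap there, at 30.5 and 32.8 against 38.8 and 85.7 CPM, and did not pass either (edgeR unadjusted p 0.0215, adjusted p 0.35). The labels do not say whether a probe reads the mutant alleles or the transgene, so these values check neither recombination nor induction.

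The first comparison asked which genes and gene groups differed between doxycycline feed and normal feed in whole sections. Genes of the gastric surface (pit) mucous cell rose as a list at camera's preset correlation, and mucus-processing and duct genes rose with them. At an estimated correlation none of these calls held (camera adjusted p 0.640 for each). Acinar genes, which encode digestive enzymes, fell as a list at the preset correlation, and so did T cell and B cell genes. With an estimated correlation these were not called either (camera adjusted p 0.640 for each), and the T and B cell calls also ended without the lymphoid region. Gastric pit genes made up 2.04% and 3.12% of UMIs with normal feed, 7.40% in doxycycline feed 1 and 22.7% in doxycycline feed 2. Acinar genes made up 52.9% and 27.5% with normal feed, 32.0% in doxycycline feed 1 and 0.225% in doxycycline feed 2. The groups overlapped in acinar share, with doxycycline feed 1 between the normal sections. Confidence bounds of these shares lay within 0.04 percentage points. The shares of duct genes (0.171% and 0.461% with normal feed against 0.435% and 0.797%) overlapped between groups. So did those of B and plasma cell genes (0.0542% and 0.0976% against 0.0242% and 0.0661%). The shares of mucus-processing genes (0.0882% and 0.125% against 0.164% and 0.359%) and of T and NK cell genes (0.0189% and 0.0301% against 0.00844% and 0.0037%) did not.

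**Figure D1:**
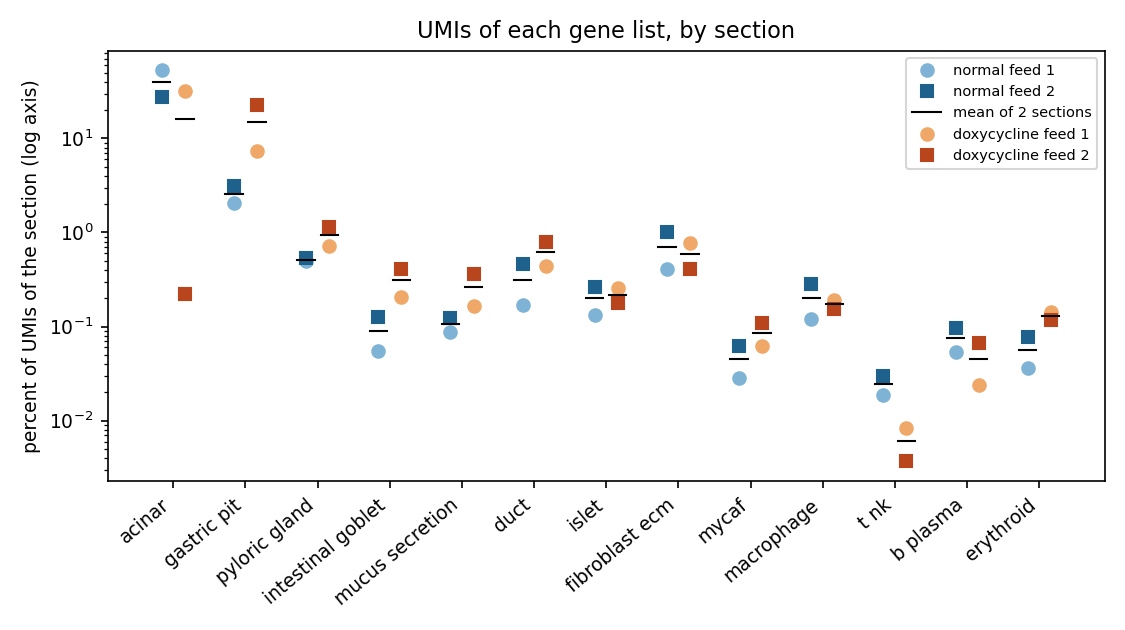
Share of each section's UMIs (percent, log axis) from 13 gene lists; points are the 4 sections and lines the mean of each group's 2 sections. The gastric pit list is at 7.40 and 22.7% with doxycycline feed and at 2.04 and 3.12% with normal feed, and the acinar list is at 0.225% in doxycycline feed 2.

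All 11 gastric pit members had positive log2 differences, with a median of 3.86 (camera adjusted p 6.09e-12). With an estimated correlation the camera adjusted p was 0.640, and 0 of the 34 lists were called. That setting has few residual degrees of freedom, and how often it would call a changed list was not simulated. Gkn1, a gastrokine secreted by stomach surface cells (chromosome 6, 87345653 to 87350915), was at 1248 and 2767 CPM with normal feed and 9202 and 107000 CPM with doxycycline feed. Its neighbour Gkn2 was at 532 and 1305 against 5188 and 44300 CPM. Tff1, a trefoil peptide, was at 18270 and 26240 against 57870 and 61600 CPM. Psca, a surface antigen of this list, had the smallest p of its members, at 7.62 and 16.2 against 55.5 and 1662 CPM. Of the 11 members, 0 passed in edgeR over all genes tested and 9 when adjusted over the list alone. Without doxycycline feed 2 the median was 1.75 (camera adjusted p 1.86e-34), and without doxycycline feed 1 it was 4.69.

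Genes of mucus folding and glycosylation had a median log2 difference of 1.94, positive in 9 of 12 members (camera adjusted p 0.000726, or 0.640 with an estimated correlation). Agr2, a folding factor of mucins, was at 11.4 and 23.3 CPM with normal feed and 50.7 and 507 CPM with doxycycline feed. Galnt7, a glycosyltransferase, was at 30.9 and 74.1 against 124 and 455 CPM. Erp27, which is also a pancreatic gene, was at 388 and 237 against 268 and 1.89 CPM. In edgeR 0 members passed over all genes tested and 5 when adjusted over the list alone. Without doxycycline feed 2 the median was 0.78. Duct and general epithelial genes had a median of 1.35, positive with TMM in all 10 members tested, with total counts in 9 and with upper quartile factors in 8 (camera adjusted p 0.000419, or 0.640 with an estimated correlation). This median was 0.36 without doxycycline feed 2. Krt19 was at 218 and 625 against 831 and 3905 CPM, and the chloride channel Cftr at 3.76 and 9.02 against 10.8 and 94.8 CPM. Epcam was at 731 and 1406 against 1262 and 593 CPM, lower in the mean of doxycycline feed, with a log2 difference of 0.04 ± 0.86 SE after TMM. No duct member (0 of 10) passed in edgeR over all genes or adjusted over the list alone. With only genes well above the background floor, which was 0.399 CPM in doxycycline feed 2, the duct list was not called.

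Acinar genes had a median log2 difference of -1.57, negative in 23 of 25 members (camera adjusted p 1.98e-09, or 0.640 with an estimated correlation). Ctrb1, a chymotrypsin precursor, was at 257400 and 162200 CPM with normal feed, 211800 CPM in doxycycline feed 1 and 1197 CPM in doxycycline feed 2. Cela2a, an elastase, was at 86990 and 29830 against 26370 and 133 CPM. Bhlha15, a transcription factor of secretory cells, was at 20.1 and 14.6 against 13.3 and 1.77 CPM. The median was -0.56 without doxycycline feed 2, -6.37 without doxycycline feed 1 and -0.70 without normal feed 1. In edgeR 0 members passed over all genes tested and 0 when adjusted over the list alone.

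T and NK cell genes had a median of -1.53, negative in 12 of 13 members (camera adjusted p 1.86e-07). B and plasma cell genes had a median of -1.71, negative in 7 of 8 members (camera adjusted p 1.04e-06). With an estimated correlation the camera adjusted p was 0.640 for both lists. Ccr7, a homing receptor of lymphocytes, was at 33.3 and 49.2 CPM with normal feed and 9.80 and 3.29 CPM with doxycycline feed. Trac, the T cell receptor alpha constant region, was at 27.3 and 60.8 against 9.66 and 8.72 CPM. Cd79a, of the B cell receptor, was at 193 and 197 against 33.3 and 13.7 CPM. The antibody joining chain Jchain was at 112 and 432 against 132 and 583 CPM. In edgeR 0 members of either list passed over all genes tested, and 3 T and NK cell members and 6 B cell members passed adjusted over the list alone. Without the region led by Ighg3 and Cd79a, left out after the data were examined, neither list was called, with medians of -0.64 and -0.65 (camera adjusted p 0.119 and 0.306). That region was picked for the highest share of UMIs from these lists. Doxycycline feed 2 held 0 spots of it, since its spots formed regions of their own, so nothing was taken from this section. B and plasma cell genes were at 0.13% and 0.198% of UMIs in its regions led by Penk and by Lcn2, which stayed in. Without doxycycline feed 1 the B cell list was not called either (camera adjusted p 0.115).

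A further 6 lists passed in camera at the preset correlation, and each had an adjusted p of 0.640 with an estimated one. Contractile fibroblast genes had a median of 1.29 (8 of 10 members positive, adjusted p 0.0361 by camera), with Acta2 at 4.17 and 14.7 against 8.46 and 92.9 CPM. Pyloric gland genes had a median of 0.92 (10 of 13 positive, camera adjusted p 0.0361), with Gkn3 at 68.5 and 123 against 197 and 1133 CPM. ERK output genes had a median of 0.75 (9 of 10 positive, camera adjusted p 0.0409), with Phlda1 at 36.3 and 107 against 133 and 282 CPM. Erythroid genes had a median of 1.30 (4 of 4 positive, camera adjusted p 0.0144). Islet genes had a median of 0.77 (12 of 14 positive, camera adjusted p 0.0285). Within this list Ins1 was at 518 and 781 against 764 and 116 CPM, and the glucagon gene Gcg at 33.5 and 15.2 against 113 and 269 CPM. Adipocyte genes had a median of -1.15 (8 of 9 negative, camera adjusted p 0.0144), with Fabp4 at 71.0 and 79.3 against 59.6 and 11.95 CPM. In edgeR 0 members of these 6 lists passed, over all genes or adjusted over the list alone. As shares of UMIs, ERK output genes (0.0335% and 0.0754% with normal feed against 0.0731% and 0.0934%) and islet genes (0.133% and 0.265% against 0.256% and 0.177%) overlapped between groups. Those of pyloric gland and erythroid genes did not. For contractile fibroblast genes (0.0281% and 0.0627% against 0.0628% and 0.108%) normal feed 2 and doxycycline feed 1 were nearly equal. For adipocyte genes (0.0126% and 0.0166% against 0.0123% and 0.00233%) normal feed 1 and doxycycline feed 1 were. The counting intervals of these near-equal sections overlapped, so neither list was clearly apart between groups. Leaving out a single section ended every one of these calls in at least 1 case. Without doxycycline feed 2, the pyloric gland, contractile fibroblast and adipocyte lists were not called. Without doxycycline feed 1 or without normal feed 1, the pyloric gland, contractile fibroblast, ERK output, islet and erythroid lists were not called. Sex as a covariate ended the pyloric gland, contractile fibroblast and adipocyte calls, and total counts or upper quartile factors the ERK output call. Without the lymphoid region the pyloric gland, contractile fibroblast, ERK output and islet lists were not called. Over genes well above the background floor none of them was called, the adipocyte list having too few members left for a test. That floor was 0.399 CPM in doxycycline feed 2 and 4.16 CPM or more in the others.

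The other 22 lists did not pass in camera (adjusted p 0.0846 to 0.83). The nearest to the threshold were the intestinal goblet list (median 1.66, camera adjusted p 0.0846), glycolysis and hypoxia (0.62, 0.0856), unfolded protein response (0.55, 0.102) and hepatocyte genes (-0.67, 0.112). Medians of the Reg and injury, cAMP response, immediate early, cell cycle and tuft lists were -0.80, 0.40, 0.33, -0.32 and 0.48. Those of interferon, Wnt, fibroblast, inflammatory fibroblast and smooth muscle genes were 0.40, -0.29, 0.38, -0.34 and 0.56. Macrophage, neutrophil, endothelial, nerve, mesothelial, acid-secreting stomach and enterocyte genes had medians of 0.31, 0.18, 0.68, -0.57, -0.23, -0.54 and -1.15. The hepatocyte, nerve, acid-secreting stomach and enterocyte lists held few UMIs, such as 0.00522% and 0.0058% with normal feed for hepatocyte genes. Their negative medians cannot be told from the lower background floor of doxycycline feed 2 (0.399 CPM, against 4.16 CPM or more). The share of the acid-secreting stomach list was highest there, at 0.0202%. Basal and squamous genes had a median of -0.69 and a mean of 0.13, with Ly6d at 47.2 and 65.8 against 63.9 and 886 CPM. With upper quartile factors, which moved the median of all genes to -0.65, the fibroblast, macrophage, neutrophil, endothelial, smooth muscle, interferon, tuft, cAMP, immediate early, glycolysis and unfolded protein medians were below 0. In the enterocyte list 1 member passed in edgeR adjusted over the list alone, and in the other lists of this group 0 did.

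No single gene passed in whole sections: edgeR called 0 of 19143 genes (smallest adjusted p 0.627), with 1514 at an unadjusted p under 0.05. DESeq2 called 333 higher and 9 lower, and gave no adjusted p for 13732 genes, while limma on mean CPM per spot called 21 higher and 20 lower. With sex as a covariate the difference rested on doxycycline feed 1 against both normal sections, since only doxycycline feed 2 was female. The 5 higher genes with the smallest p were Psca (log2 difference 6.77 ± 1.61 SE), Tcf23, Atp8a2, Ern2 and Mucl3, none of which passed in edgeR. Mucl3, a mucin-related gene, was at 7.52 and 13.6 CPM with normal feed and 35.7 and 2129 CPM with doxycycline feed, and Ern2, a stress sensor of mucous cells, at 0.407 and 0.722 against 1.87 and 50.9 CPM. Values under the background floor of 4.57, 4.47, 4.16 and 0.399 CPM, such as the first 3 of Ern2, cannot be told from background. The 5 lower genes were Ighg3, Cd79a (log2 difference -2.90 ± 0.71 SE), Lck, Cd5 and Cd209b, none of which passed. Lck, a T cell kinase, was at 57.6 and 66.3 against 10.9 and 4.93 CPM. Leaving out doxycycline feed 1 gave 13817 genes in edgeR, and leaving out doxycycline feed 2 gave 9 higher and 19 lower. The common dispersion with all sections was 0.368.

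The second comparison asked what differed within the keratin-rich spots of each section, 295 and 333 spots with normal feed and 322 and 247 with doxycycline feed. These held 754403, 1434988, 2398551 and 6220969 UMIs. Their lowest keratin share was 0.304% and 0.534% of UMIs with normal feed and 0.542% and 0.776% with doxycycline feed. Acinar genes made up 8.47% and 3.24% against 2.79% and 0.0319% of their UMIs. The spots were thus not matched for epithelium between sections, and differences among them can also reflect tissue mix. Gastric pit genes rose as a list there too, with a median log2 difference of 3.03 and positive values in all 11 members (camera adjusted p 1.70e-12). With an estimated correlation the camera adjusted p was 0.718, and 0 of the 33 lists were called. Gkn1 was at 6987 and 5076 CPM with normal feed and 26700 and 112400 CPM with doxycycline feed. Gkn2 was at 2916 and 2148 against 15020 and 47580 CPM, and Psca at 26.5 and 27.2 against 174 and 2123 CPM. Tff1, in contrast to whole sections, overlapped between groups, at 113000 and 56030 against 147300 and 72790 CPM, a contrast that was not itself tested. In edgeR 0 members passed over all genes tested and 9 when adjusted over the list alone. Without doxycycline feed 2 the median was 1.94 (camera adjusted p 3.37e-30).

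**Figure D2:**
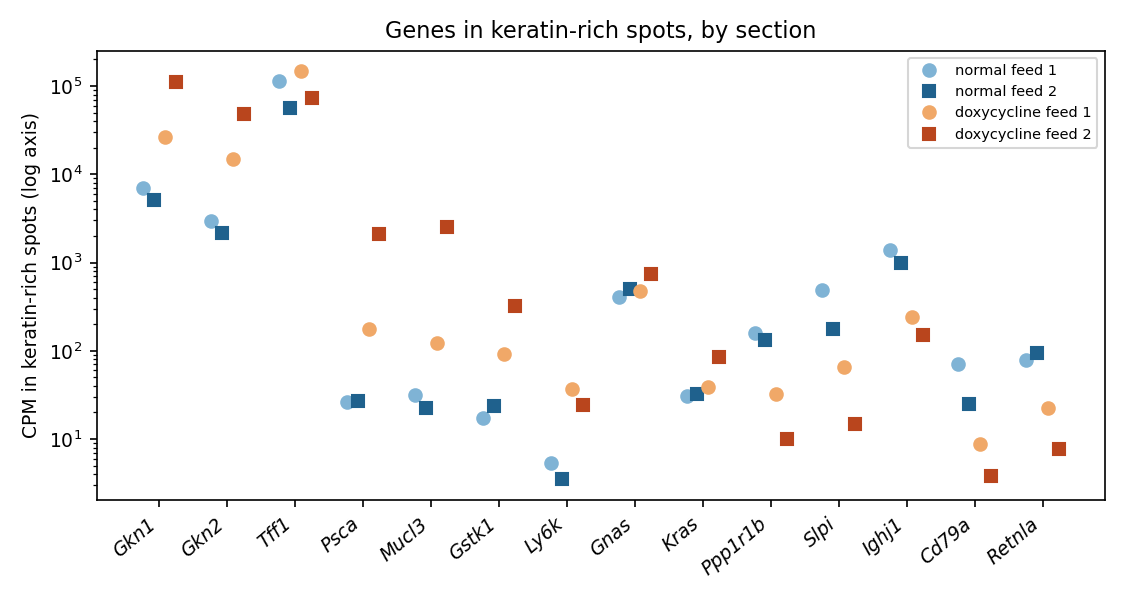
CPM of 14 named genes in keratin-rich spots (log axis), with 1 point for each of the 4 sections. Gkn1, Gkn2 and Psca are higher in both doxycycline sections than in both normal ones, Tff1 overlaps between groups, and Gnas is at 475 and 739 CPM with doxycycline feed against 407 and 505 CPM.

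In the same spots, mucus-processing genes had a median log2 difference of 1.74, positive in 9 of 11 members (camera adjusted p 0.00403). The mucin gene Muc1 was at 10.6 and 17.4 CPM with normal feed and 27.1 and 382 CPM with doxycycline feed, and the mucin-branching enzyme gene Gcnt3 at 106 and 119 against 258 and 350 CPM. Acinar genes had a median of -1.68, negative in 23 of 24 members (camera adjusted p 6.45e-10), with Ctrb1 at 59700 and 24760 against 20480 and 97.6 CPM. Reg family and injury genes had a median of -1.38, negative in 7 of 9 members (camera adjusted p 0.0139), with Reg1 at 3213 and 2165 against 943 and 505 CPM. Clu, in the same list, was at 15830 and 32020 against 31800 and 26340 CPM. T and NK cell genes had a median of -1.13, negative in 7 of 8 members (camera adjusted p 0.0108), with Cd3d at 21.2 and 15.3 against 4.59 and 1.93 CPM. The background floor was 4.16 CPM in doxycycline feed 1, and too few members of this list lay well above the floor for a test there. With an estimated correlation none of these lists was called (camera adjusted p 0.718 for each). In edgeR 6 mucus-processing members and 0 members of the acinar, Reg and T cell lists passed adjusted over the list alone, and 0 over all genes tested. Without doxycycline feed 2 the T cell list was not called (median -0.35, camera adjusted p 0.0604), and the mucus, acinar and Reg medians were 0.64, -0.72 and -0.65. Without doxycycline feed 1 the acinar median was -5.45, and without normal feed 1 the acinar, Reg and T cell medians were -0.58, -0.90 and -0.69.

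The other 28 lists tested in keratin-rich spots did not pass in camera (adjusted p 0.051 to 0.954). Nearest were B and plasma cell genes (median -0.98, camera adjusted p 0.051), the intestinal goblet list (1.17, 0.069), and duct, cell cycle and unfolded protein genes (0.81, -0.52 and 0.69, each 0.074). Adjusted over the list alone, edgeR passed 2 intestinal goblet, 4 duct and 1 B cell member. Pyloric gland genes had a median of -0.25, with Tff2 at 9203 and 7961 CPM with normal feed and 9136 and 7081 CPM with doxycycline feed. For the cAMP response list the median was 0.16 while the direction of the camera test was down.

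No single gene passed in keratin-rich spots: edgeR called 0 of 15238 (smallest adjusted p 0.31), with 1830 at an unadjusted p under 0.05. DESeq2 called 276 higher and 5 lower, and gave no adjusted p for 9454 genes. The 5 higher genes with the smallest p were Psca (log2 difference 6.30 ± 1.15 SE), Gkn2 (4.42 ± 0.82 SE), Gstk1, Mucl3 and Ly6k, none of which passed in edgeR. Mucl3 was at 31.8 and 22.3 against 121 and 2496 CPM, and Gstk1, a glutathione transferase, at 17.2 and 23.7 against 92.6 and 324 CPM. The 5 lower genes were Ppp1r1b, Slpi, Ighj1, Cd79a and Retnla, none of which passed. Slpi, a secreted protease inhibitor, was at 488 and 176 against 65.0 and 14.6 CPM, and the antibody heavy chain segment Ighj1 at 1371 and 978 against 239 and 153 CPM. With no filter on low counts edgeR called 625 higher and 3 lower. Leaving out doxycycline feed 1 gave 8535 genes in edgeR, leaving out doxycycline feed 2 gave 21, and leaving out normal feed 1 gave 2.

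Clustering of spots gave 14 regions and asked how the sections were composed. In 3 regions over 0.5 of the UMIs came from the acinar list, and these regions, led by Reg3a, by Ctrc and by Ins1 with Ctrc, held 62.6% and 30.01% of spots with normal feed. They held 24.4% in doxycycline feed 1 and 0 of 2468 spots in doxycycline feed 2, which allows up to 0.122%. The group means were 46.3 ± 23.0% and 12.2 ± 17.3% (SD, n = 2). A region led by Ins2, Ins1 and Chga, where gastric pit genes made up 12.8 to 20.8% of UMIs, held 5.69% and 6.31% of spots with normal feed and 23.1% in doxycycline feed 1. A lymphoid region led by Ighg3, Cd79a, Ighg2c, Enpp2 and Ptprcap held 8.07% and 14.0% with normal feed, 1.33% in doxycycline feed 1 and 0 of 2468 spots in doxycycline feed 2. Spots of doxycycline feed 2 clustered apart from the others, so this 0 does not show that it lacked lymphoid tissue. Confidence bounds of these shares lay within 2.0 percentage points.

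Doxycycline feed 2 fell almost entirely in regions of its own, with 2454 of 2468 spots (99.4%, interval 99.1 to 99.7%). The largest of these was led by Psca, Mucl3, 2210407C18Rik, Gkn1 and Gkn2 and held 57.2% of its spots, with Gkn1 at 137000 CPM and gastric pit genes at 28.8% of UMIs. A region led by Penk, Ccn2, Col12a1, Thbs1 and Fn1, genes of matrix and its stimulation among them, held 33.4%. Gastric pit genes made up 13.4% and fibroblast genes 0.688% of its UMIs in this section. Regions led by Des and Hba-a2 and by Lcn2 and Cxcl5 held 5.47% and 3.40%. The matrix region of the other sections, led by Col5a1, Col1a2, Col4a1, Ccn5 and Emilin1, held 5.15% and 12.4% with normal feed and 21.2% in doxycycline feed 1. Its make-up differed from that of the region led by Penk, with gastric pit genes at 1.45 to 2.16% and fibroblast genes at 2.34 to 2.92% of UMIs. No test was made of these shares, since 2 against 2 sections cannot give an exact permutation p below 0.333.

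**Figure D3:**
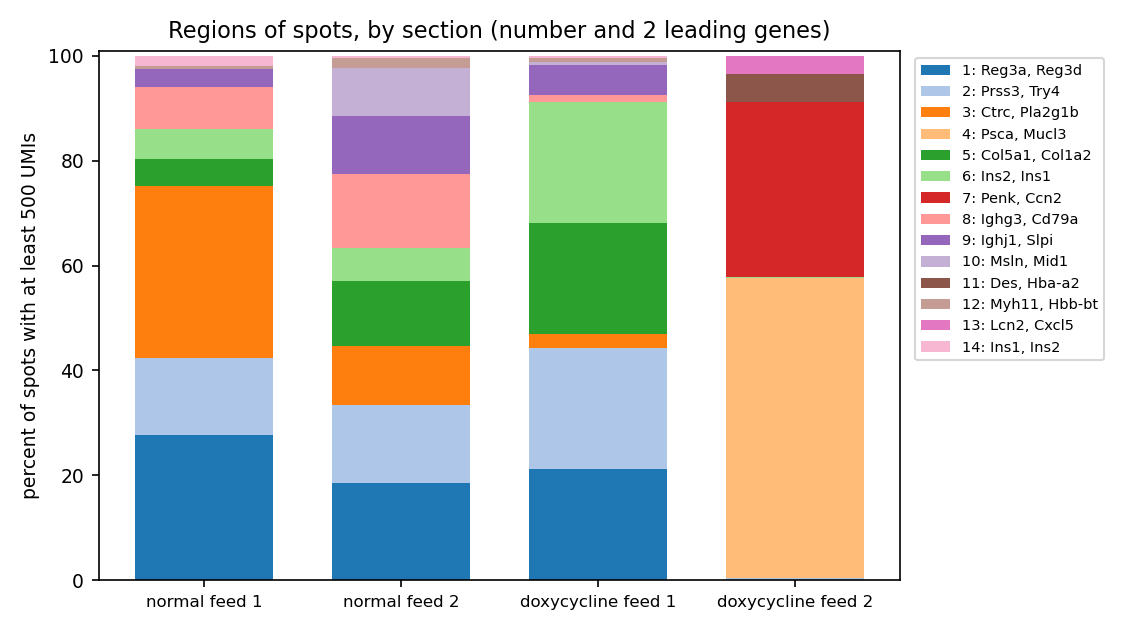
Percent of spots with at least 500 UMIs in each of 14 regions, as 1 stacked bar for each of the 4 sections, with regions named by number and leading genes. Doxycycline feed 2 shares almost no region with the others (99.4% of its spots are in regions of its own), and region 3, led by Ctrc, takes 32.9 and 11.2% with normal feed and 2.64% of doxycycline feed 1, while region 1, led by Reg3a, takes 27.7 and 18.5% and then 21.3%.

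Within regions, doxycycline feed could be compared for doxycycline feed 1 alone, against both normal sections. In the region led by Ins2 and Ins1, where gastric pit genes were high, edgeR called 8 genes higher and 1 lower of 12659. The higher genes were Gkn2 (log2 difference 1.85 ± 0.22 SE, adjusted p 1.52e-12 in edgeR), Gkn1 (1.51 ± 0.19 SE), Psca, Muc5ac, Tff3, Gstk1, Hbb-bs and Hba-a2. Muc5ac, the main mucin of stomach surface cells (chromosome 7, 141788958 to 141819227), was at 563 and 530 CPM in the normal sections and 1313 CPM in doxycycline feed 1. The lower gene was Ighj1 (log2 difference -1.64 ± 0.39 SE). DESeq2 called 2 genes there, and total counts without TMM gave 14. The gastric pit list had a median of 1.28 in this region and the duct list 0.12. Medians of other lists there were 1.92 for erythroid, -0.47 for islet, -0.44 for fibroblast, -0.56 for B and plasma cell and -0.51 for tuft genes. Mucus-processing, intestinal goblet and acid-secreting stomach genes had medians of 0.55, 0.14 and -0.73, and each of these 8 lists was past the threshold of camera at the preset correlation, the only one run. The gastric pit median was positive in all 7 regions, at 1.31 in the lymphoid region (6 members tested) and 1.03 and 0.56 in the acinar regions led by Ctrc and by Reg3a. As a share of UMIs, which the most abundant members set, the list was at 17.8% and 12.8% with normal feed and 20.8% in doxycycline feed 1 in the region led by Ins2 and Ins1, and at 0.0532% and 0.0791% against 0.123% in that led by Ctrc. In the region led by Reg3a it was at 0.929% and 0.614% against 0.693%, doxycycline feed 1 lying between the normal sections. In whole sections acinar genes were lower as a list with doxycycline feed. Their share in doxycycline feed 1 (32.0%) nevertheless lay between those of the normal sections (52.9% and 27.5%). Within most of these regions acinar genes had positive medians in doxycycline feed 1. The medians were 0.37 in the region led by Reg3a, 2.07 in the lymphoid region, and 0.22 and 0.39 in the regions led by Col5a1 and Col1a2 and by Ighj1 and Slpi. In the acinar region led by Ctrc the median was 0.097. It was -0.074 in the region led by Prss3 and -0.033 in that led by Ins2 and Ins1. The lymphoid region had 43 spots in doxycycline feed 1, with acinar genes at 6.45% of UMIs against 1.69% and 0.452% and an adipocyte median of 1.82, so its tissue mix differed between sections. T and NK cell genes had a median of -2.49 there and B and plasma cell genes one of -0.91, both past the threshold of camera at the preset correlation. In the other 6 regions edgeR called 0 (region led by Reg3a, with 215 at an unadjusted p under 0.05 and 0 by DESeq2) to 49 genes, the most in the lymphoid region, where DESeq2 called 0.

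Co-occurrence asked which gene groups shared spots. Across spots thinned to 1000 UMIs, gastric pit and duct genes went together in 3 sections, with a rho of 0.651 and 0.631 with normal feed and 0.603 in doxycycline feed 1, against 0.076 in doxycycline feed 2. Gastric pit and intestinal goblet genes went together in all 4 sections (rho 0.599, 0.659, 0.760 and 0.537). Gastric pit and pyloric gland genes had a rho of 0.456, 0.569 and 0.557, and -0.155 in doxycycline feed 2. Gastric pit and fibroblast genes had a rho of 0.585 and 0.308 with normal feed and -0.110 and -0.531 with doxycycline feed, with means of 0.447 ± 0.196 and -0.321 ± 0.298 (SD, n = 2). Macrophage genes followed, at 0.331 and 0.0324 against -0.131 and -0.456. Acinar genes had a rho with gastric pit genes of -0.546 and -0.121 against -0.609 and -0.00469, the last in a section where acinar genes were 0.225% of UMIs. Spots hold several cells and RNA can spread between spots, so a rho describes spots and not cells. The scores are shares of a spot's UMIs, so a rho between other lists also depends on the acinar share. That share differed between sections. Acinar and fibroblast genes had a mean rho of -0.49 with normal feed and -0.11 with doxycycline feed. In doxycycline feed 2 gastric pit genes were 22.7% of UMIs, a share that can by itself lower their rho with other lists. Differences in rho between groups were not adjusted for the acinar or the gastric pit share.

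**Figure D4:**
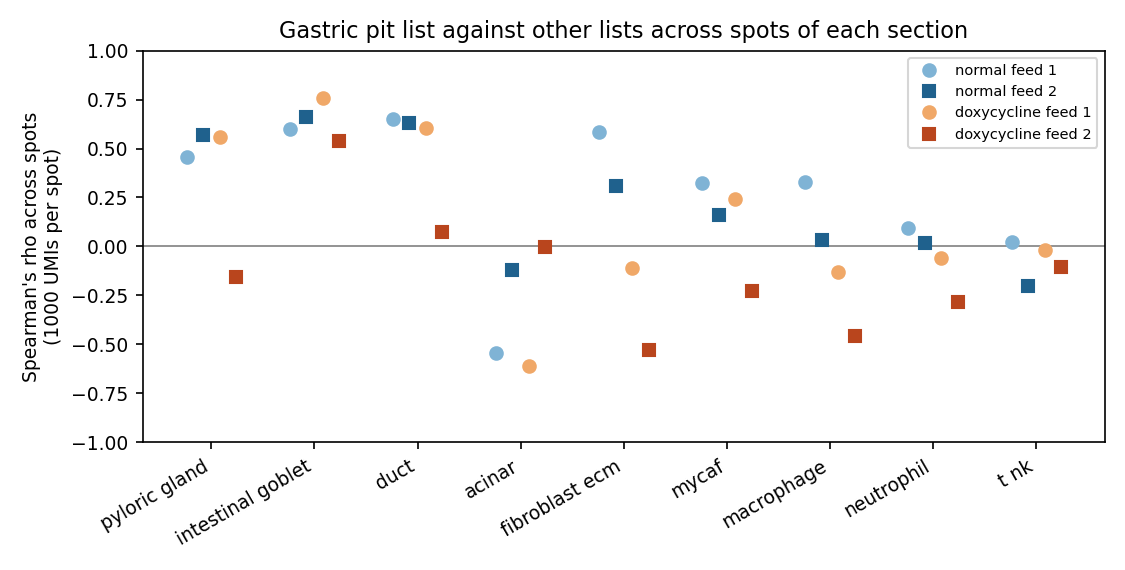
Spearman's rho across the spots of each section between the gastric pit list and 9 other lists (spots thinned to 1000 UMIs), with 1 point for each of the 4 sections. The rho with fibroblast genes is 0.585 and 0.308 with normal feed and -0.110 and -0.531 with doxycycline feed, and the rho with duct genes is 0.076 in doxycycline feed 2 and at least 0.603 in the others.

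At 1000 UMIs per spot, Gkn1 was found in 29.4% and 43.6% of spots with normal feed, 67.3% in doxycycline feed 1 and 98.3% in doxycycline feed 2. In spots of acinar regions, the shares were 13.3%, 17.9% and 26.2% in the first 3 sections, and doxycycline feed 2 had no such spots. Median depths before thinning were 2976, 3732.5 and 5063 UMIs in those sections and 3420, 3912.5 and 8863 in their acinar regions. The mix of acinar regions differed between these sections. The region led by Reg3a, with gastric pit genes at 0.614 to 0.929% of UMIs, held 27.7%, 18.5% and 21.3% of their spots. That led by Ctrc, with gastric pit genes at 0.0532 to 0.123%, held 32.9%, 11.2% and 2.64%. Shares in acinar regions depend on this mix, so they measure neither RNA spread nor diet by themselves. Muc5ac was found in 6.94% and 10.7% against 28.5% and 84.8% of spots, with 1.66%, 3.25% and 5.61% in acinar regions. Tff1 was found in 56.3% and 70.6% against 90.02% and 97.2%, with 42.8%, 55.0% and 68.8% in acinar regions. Gnas was found in 24.4% and 34.6% against 33.8% and 54.1% of spots, and Kras in 1.49% and 3.34% against 3.30% and 7.05%. Ctrb1, the chymotrypsin precursor gene, was found in 99.4%, 94.1% and 99.0% of spots and in 10.6% in doxycycline feed 2.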

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

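The alternatives with a restriction to genes above background, without the lymphoid region or with keratin-rich spots of at least 2000 UMIs, and the results on co-occurrence and on Gkn1 followed here, were chosen after the data were examined. In all, 565 alternatives were computed for the results followed here, and 0 of these changed direction. The results are counts, shares of spots, co-occurrence, the model's genes, the genes with the smallest p and lists called in the main comparison. Counts have no direction and could only stay or move. The genes with the smallest p and the called lists were picked from these same data, so the lack of turns is no independent support. Other genes and lists did turn. Of 40 further named members of called lists in whole sections, 8 turned under at least 1 alternative: Epcam (0.04, from -0.46 to 0.31), Ins1, Ins2, Chga, Dusp6, Acta2 (3.04, from -0.10 to 3.93), Jchain and Car3. In keratin-rich spots 1 of 17 did, Trac. The fibroblast and macrophage lists, not called, turned with upper quartile factors. Of the leading results 47 stayed the same under an alternative, 2 weakened and 23 moved. Of the other results 362 stayed the same, 43 weakened, 77 strengthened and 11 moved. Those that moved were not single genes or lists, to which that label did not apply. The count of genes in whole sections was 0 with edgeR (1514 at an unadjusted p under 0.05). It was 342 with DESeq2, 12 with total counts, 31 with sex as a covariate and 41 with limma, and 0 to 13817 with each section left out, the highest without doxycycline feed 1. In keratin-rich spots it was 0 with edgeR (1830 at an unadjusted p under 0.05). It was 281 with DESeq2, 2 with total counts and 628 with no filter on low counts, and 0 to 8535 with each section left out, the highest again without doxycycline feed 1. Lists called in whole sections numbered 12, and 0 with an estimated correlation, 7 with genes above background, 6 without the lymphoid region, and 6 to 14 with each section left out. In keratin-rich spots they numbered 5, and 0 with an estimated correlation, 10 and 8 in the top 5% and 20% of spots, 8 with genes above background, and 7 to 10 with each section left out. The gastric pit median stayed at 3.86 in whole sections and 3.03 in keratin-rich spots with an estimated correlation, where camera no longer called it (adjusted p 0.640 and 0.718). Across the other alternatives the gastric pit list was called in each, but all of these used camera's preset correlation. The estimated correlation was run on the main fits only and was not part of the simulations. These calls therefore do not show that the list would pass under an estimated correlation. The cause of the changes in these counts was not tested, except that the sets with genes above background hold fewer genes (5900 and 7567). A fit without a section leaves its group with 1 section, which is assumed to vary like the others. Total counts moved the median log2 difference of all genes from -0.05 to -0.30 in whole sections and from 0.03 to -0.60 in keratin-rich spots, and upper quartile factors to -0.65 in whole sections.

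The difference in the share of spots in acinar regions, doxycycline minus normal feed, was -34.1 percentage points and -31.5 to -33.8 with other clustering settings. The share of doxycycline feed 2 spots in regions of its own ran from 94.1 to 99.7%. The difference in rho between gastric pit and fibroblast genes was -0.77 at 1000 UMIs per spot and -0.67, -0.81 and -0.84 at 500 UMIs, 2000 UMIs and without thinning. The leave-one-out alternatives planned within regions were not run, since the test within regions could not be run in all 4 sections. Depth limited the share of spots in which a gene was found. For Kras the difference, doxycycline minus normal feed, was 2.76 percentage points at 1000 UMIs per spot, 1.55 at 500 UMIs, 6.57 at 2000 UMIs and 39.6 without thinning. For Gnas it was 14.5, 11.3, 20.5 and 28.5.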

Other observations

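Hemoglobin genes were higher in doxycycline feed 1 in each of the 7 regions where this section was compared with both normal ones. The erythroid list had a median log2 difference of 1.44 to 2.93 there, and in the region led by Ins2 and Ins1 the hemoglobin genes Hbb-bs (2.81 ± 0.41 SE) and Hba-a2 (2.17 ± 0.39 SE) passed in edgeR. In whole sections Hba-a2 was at 225 and 415 CPM with normal feed and 773 and 676 CPM with doxycycline feed, and did not pass. The estimated correlation was not run for lists within regions.

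Normal feed 2 held 304 spots (9.14%) in a region led by Msln, Mid1, Mmp7, Scara3 and Tacstd2, against 2 spots in normal feed 1 and 24 in doxycycline feed 1. Doxycycline feed 2 held 84 spots (3.40%) in a region led by Lcn2, Cxcl5, S100a9, Mmp7 and Olfm4, genes of neutrophils and inflamed epithelium among them, with Lcn2 at 3522 CPM against 110 elsewhere. Muscle-led regions, with Des or Myh11 among their leading genes, held 0.474% and 2.04% of spots with normal feed, 0.652% in doxycycline feed 1 and 5.47% in doxycycline feed 2.

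For the weighing that follows, the tests of loss of acinar tissue, of stomach tissue, of fewer acinar UMIs and of a larger epithelial area were chosen after the result was seen. The test of stomach tissue replaced earlier forms that rested on values near the background, the first of which had come out undecided. That of fewer acinar UMIs replaced one in which leaving the acinar list out moved almost nothing. The test of loss of acinar tissue was added to one in muscle-led regions that was set beforehand.

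Doxycycline feed 2 stood apart from the other 3 sections. A lower background alone is argued against, since over 2577 genes with a mean of at least 50 CPM its r with doxycycline feed 1 was 0.401, against 0.954 between doxycycline feed 1 and normal feed 2. Loss of acinar tissue alone is argued against, since in keratin-rich spots without acinar genes its highest r with another section was 0.644 over 3376 genes, against at least 0.88 among the others. The earlier test, in muscle-led regions, did not decide (the SD of log2 differences to normal feed 2 was 1.28 times that of doxycycline feed 1). A section-wide shift from RNA quality or the library stays open. Its differences in muscle-led and in gastric-pit-rich regions went together across 1557 genes (r 0.744), with doxycycline feed 1 in both references. Any difference of this mouse that reaches all tissues, or RNA spread between spots, would also give a positive r. The r therefore does not point to RNA quality or the library. The sex of the mouse and its response to doxycycline feed stay open as untested.

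Gastric pit genes were higher with doxycycline feed as a list at camera's preset correlation. With an estimated correlation the list was not called (camera adjusted p 0.640 in whole sections and 0.718 in keratin-rich spots), and edgeR called 0 single genes. Oxyntic stomach tissue in the sections is argued against, since the highest of 4 parietal and chief cell genes, background included, was 0.0752% of Gkn1 in doxycycline feed 1 and 0.00298% in doxycycline feed 2; antral stomach stays open, and Ghrl, of stomach endocrine and some islet cells, was at 14.4 and 40.1 against 33.3 and 193 CPM. Fewer acinar UMIs raising all other shares is argued against, since as a share of UMIs outside the acinar list the gastric pit list was at 4.33% and 4.31% against 10.9% and 22.7%, the lower doxycycline section at 2.52 times the higher normal one. A larger epithelial area alone in doxycycline feed 1 cannot be told apart, since the median was 1.28 within the region led by Ins2 and Ins1 (duct list 0.12) but also 1.03 in the acinar region led by Ctrc, and the spots of a region can differ in tissue mix between sections, as in the lymphoid region (acinar median 2.07, gastric pit 1.31). An effect of doxycycline feed, a possible section-wide shift in doxycycline feed 2, sex and chance between 2 mice per group stay open.

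B and T cell genes were lower with doxycycline feed as lists at camera's preset correlation, and were not called at an estimated one (camera adjusted p 0.64). As a share of UMIs, B and plasma cell genes overlapped between groups, at 0.0542% and 0.0976% with normal feed against 0.0242% and 0.0661%. Lymphoid tissue in the normal sections cannot be told apart as the whole source, since without the lymphoid region the medians were -0.65 for B and plasma cell genes and -0.64 for T and NK cell genes, between the bounds set for either answer, where whole sections gave -1.71 and -1.53. The camera calls of both lists ended there with smaller differences, 5 of 8 members negative for B cell genes (7 of 8 before) and 11 of 12 for T cell genes (12 of 13 before). The region was picked for its share of these lists and held 0 spots of doxycycline feed 2. Leaving it out thus took spots from the other sections only, so smaller differences without it decide little. Within the lymphoid region, the 43 spots of doxycycline feed 1 had medians of -2.49 for T and NK cell genes and -0.91 for B and plasma cell genes, which a smaller lymphoid area alone would not give, though acinar and adipocyte genes were higher in them (medians 2.07 and 1.82), so mixed spots stay open. Whether lymph node entered the sections is not in the labels, and an effect of doxycycline feed on lymphocytes stays open and was not tested.

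Of the 1178 receptor genes taken as background, 8 were X-linked and 1163 autosomal. The median count of the X-linked ones was 0.356, 0.331 and 0.431 of the autosomal one in the 3 sections from male mice and 0.692 in doxycycline feed 2. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had 0 UMIs in doxycycline feed 2 and 30 to 438 UMIs in the other sections, which matched the sex given by the labels.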
